A study of Mus musculus with 6 samples.

How the data were processed

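RNA was sequenced from sorted mouse lung ILC2s of 2 genotypes on a NextSeq 500, per the labels. Mice received 3 intranasal injections of 1 µg IL-33 and the cells were cultured for 24 h with IL-2 and IL-7 at 10 ng/mL each. Libraries were made from 10 ng of total RNA. Whether the library kit keeps the strand is not given in the sources used here, so whether reads of overlapping and antisense genes were told apart is unknown.

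The deposited table holds estimated counts per gene made by the authors, which need not be whole and are not scaled between libraries. Between 37.9% and 47.4% of the values in a library differed from a whole number by more than 1e-09. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here. The table has 18057 genes named by symbol, and the lowest sum of a gene over the 6 libraries was 10. Libraries are the rows of the table, and each was matched to its sample by the sample description in the labels. The labels' genotype gave the groups, named control (Il7r-Cre) and Piezo1_KO (Il7r-Cre with floxed Piezo1), with 3 libraries each and the replicate number from the label. The sample titles call the control libraries WT, which does not by itself say whether they carry the driver.

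Estimated counts were rounded to whole numbers. Genes were kept by filterByExpr with the groups (14149 genes), scaled by TMM, and tested with glmQLFit and glmQLFTest in edgeR 4.0.16 (R 4.3.3) without covariates, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The biological coefficient of variation was 0.201. Standard errors of log2 fold changes are the absolute change divided by the square root of the F statistic. CPM values are TMM-scaled. The median log2 fold change of all tested genes was 0.018, so no further centring was applied. No pair of replicates agreed within sampling noise: the chi-square per gene within a group lay between 9.97 and 55.4, where 1 is the value of sampling noise alone.

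Before the data were examined, 32 gene lists were fixed for the pathways, ILC2 functions and other cell types that a lung ILC2 sort could hold. They name 874 genes, of which 777 are in the table and 730 were tested. Lists with at least 5 tested members (28) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The lists of erythroid and platelet, B and plasma cell, ILC3 and sex-linked genes were too small and have counts only. Fry, which tests whether a list's genes move on balance one way, called 9 lists, and its mixed form, which tests for change in either direction, called 25. Neither compares a list with other genes. The median and the camera direction differed in sign for YAP/TAZ targets and NK cell and ILC1 markers, neither of which camera called.

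Genes named in the text follow a rule also fixed beforehand. They are Piezo1, the genes Il5, Il13, Gata3, Il1rl1, Klf2 and Areg whatever their values, the 6 largest fold changes in each direction among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between groups (leaving out predicted genes, named Gm with digits or ending in Rik), and from each list up to 3 members past the threshold with the smallest p, or the 1 member with the smallest p where none passed. Some genes that this rule names are not reported here. Aldoc, Slc16a3 and the genes of the closing observations that the rule does not name were chosen after their values were seen. Gene positions were taken from GENCODE release M21, built on GRCm38, which is mm10, for symbols that occur there once (17579 of 18057).

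The depth per library was 13059046 to 33459904 estimated counts. A gene with 0 counts in every library of a group was given a floor of 3 counts over the group, and floors and intervals cover counting error only. The fit was tested on simulated counts drawn from these libraries with 200 changed genes. For the comparison of Piezo1_KO with control (13856 genes tested), it recovered 18% of 1.5-fold, 48% of 2-fold, 78% of 3-fold and 86% of 4-fold changes, 50 genes each, with 7 false calls among 122.

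The alternatives fixed beforehand were RLE size factors, no filter on low counts, a stricter filter (at least 1 CPM in all libraries of a group), the replicate number as a block, leaving out each library in turn, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, robust quasi-likelihood, a minimum fold of 1.5, and for the lists the estimated correlation, fry and members that no other list holds. A fit on protein-coding genes only was added after the data had been seen. With 3 libraries against 3 there are 10 splits of the libraries, and the counts of genes and lists were recomputed in each.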

Results

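Group 2 innate lymphoid cells (ILC2s) are tissue-resident lymphocytes that secrete type 2 cytokines such as IL-5 and IL-13 in response to alarmins such as IL-33. RNA was profiled in ILC2s sorted from the lungs of mice that had received 3 intranasal injections of 1 µg IL-33, after 24 h of culture with IL-2 and IL-7. Per the genotype labels, the control group carried the Il7r-Cre driver alone, though the sample titles call these libraries WT. The Piezo1_KO group carried the same driver with a floxed allele of Piezo1, which encodes a mechanically gated cation channel, so the comparison asks what losing Piezo1 changes in the transcriptome of activated lung ILC2s. Each group had 3 libraries. The total estimated count was 19658049, 33459904 and 13059046 in control replicates 1, 2 and 3 and 23549849, 29733378 and 23774230 in Piezo1_KO replicates 1, 2 and 3. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

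Piezo1 (chromosome 8, 122481698 to 122551329 in mm10, minus strand) was measured first, as a check of the labels. Its level was 247, 278 and 160 CPM (counts scaled to library size) in control replicates 1, 2 and 3 and 150, 109 and 122 CPM in Piezo1_KO replicates 1, 2 and 3. The mean was 229 ± 61.4 CPM (SD, n = 3) in control and 127 ± 20.99 CPM (SD, n = 3) in Piezo1_KO, a log2 fold change of −0.85 ± 0.21 (SE), with no overlap between the groups. The difference did not pass the threshold (adjusted p = 0.112, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested). Under 14 alternative fits the adjusted p ranged from 0.00193 to 0.464, and it passed in DESeq2 (0.00193), in limma-voom with sample quality weights (0.0157), without control replicate 3 (0.0163) and with protein-coding genes only (0.0493). A gene-level count also takes in exons outside the floxed part, so the remaining counts do not measure how much intact transcript was left.

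**Figure D1:**
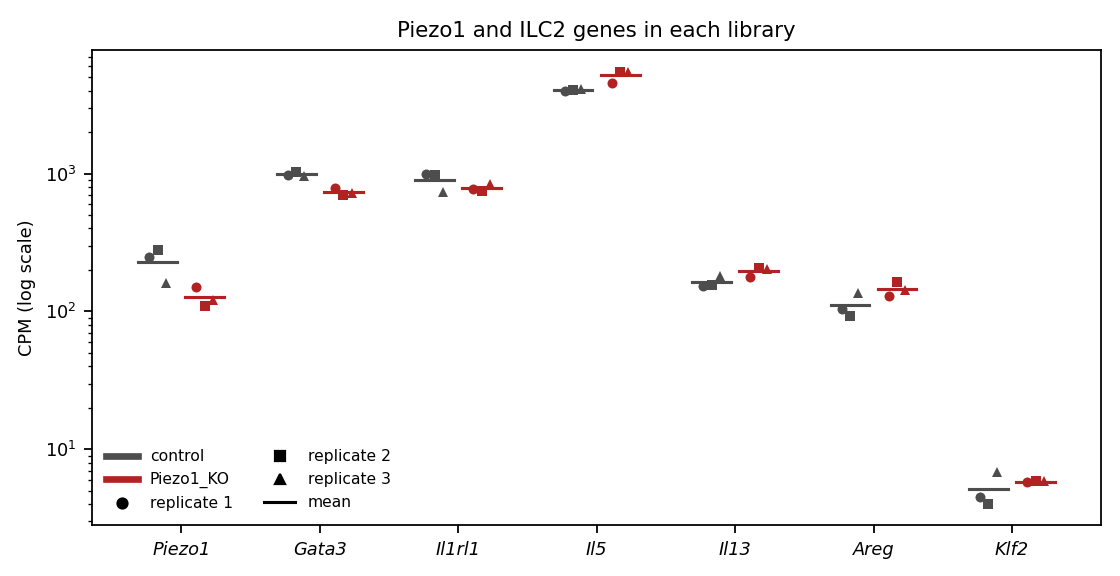
CPM on a log axis in each of the 6 libraries for Piezo1 and 6 ILC2 genes fixed before the data were examined. Symbols mark the replicate, colours the group and bars the group mean. All 3 Piezo1_KO libraries lie below the 3 control libraries for Piezo1 (150 CPM at most against 160 CPM at least) and for Gata3, and none of the 7 genes passed the threshold.

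None of the 6 ILC2 genes fixed beforehand passed the threshold. Il5, the eosinophil growth factor, was at 4038 ± 48.4 CPM in control and 5159 ± 505 CPM in Piezo1_KO (SD, n = 3), a log2 fold change of 0.35 ± 0.09 (SE) that did not pass (adjusted p = 0.120, edgeR), with no overlap between the groups, and 2 of its 14 alternative fits passed, DESeq2 (0.0220) and limma-voom (0.0406). Il13, the cytokine behind goblet cell mucus and airway smooth muscle responses, had a log2 fold change of 0.26 ± 0.11, and Areg, the epithelial repair factor amphiregulin, of 0.39 ± 0.16 (adjusted p = 0.339 and 0.328). Gata3, the lineage transcription factor, had a log2 fold change of −0.42 ± 0.09 (adjusted p = 0.0612), and 3 of its 14 alternative fits passed. The IL-33 receptor gene Il1rl1 (−0.20 ± 0.13, adjusted p = 0.570) and Klf2, a transcription factor of lymphocyte quiescence and trafficking (0.20 ± 0.24, adjusted p = 0.792), did not pass in any fit.

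Across the transcriptome, 214 of 14149 genes tested passed an adjusted p of 0.05, of which 142 were higher and 72 lower in Piezo1_KO, and 75 and 33 of these changed at least 2-fold. Among called genes with a mean log2 CPM of at least 3, the largest rises included the interferon-inducible transmembrane genes Ifitm1, Ifitm2 and Ifitm3, which lie close together on chromosome 7. Ifitm1 rose 7.24-fold, from 24.6 ± 4.55 to 178 ± 18.7 CPM (SD, n = 3). Ifitm2 rose 4.65-fold and Ifitm3 4.58-fold. Hba-a1, an alpha globin gene, rose 5.98-fold, Cdh17, a cadherin, 5.42-fold, and Penk, which encodes the opioid peptide precursor proenkephalin, 4.22-fold. The largest fall above this expression limit was in Gvin1, an interferon-inducible very large GTPase on chromosome 7, from 55.4 ± 18.9 to 1.05 ± 0.26 CPM (SD, n = 3), a 53.5-fold difference. Gbp6, a guanylate-binding protein, was 4.25-fold lower and Upp1, uridine phosphorylase, 4.24-fold lower. Kctd12 (3.29-fold), Gas7 (2.93-fold) and Lmna, which encodes the nuclear lamins A and C (2.56-fold), completed the 6 largest falls above the limit, and some called genes below it, such as Tbx21 and Entpd1, fell by more than several of these. Adjusted p for these 12 genes lay between 0.000333 and 0.01002 (edgeR). Hba-a1, the Ifitm genes, Gvin1 and Gbp6 have close paralogs, so how reads were divided within each family is uncertain.

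All 214 genes had no overlap between the groups, which held for 20.6% of all tested genes against 10% by chance. At an unadjusted p under 0.05 there were 892 genes higher and 977 lower, or 1869 in all, where 707 would be expected by chance. The split of control replicates 1 and 2 and Piezo1_KO replicate 1 against the other libraries gave 1875 such genes, so this count does not set the real groups apart. The count of 214 rose to 593 in DESeq2, 439 in limma-voom and 392 with protein-coding genes only, and fell to 34 without control replicate 1, 35, 33 and 53 without Piezo1_KO replicates 1, 2 and 3. In data simulated on these libraries, the test recovered 18% of 1.5-fold changes and 86% of 4-fold changes, so most small changes would not be called.

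**Figure D2:**
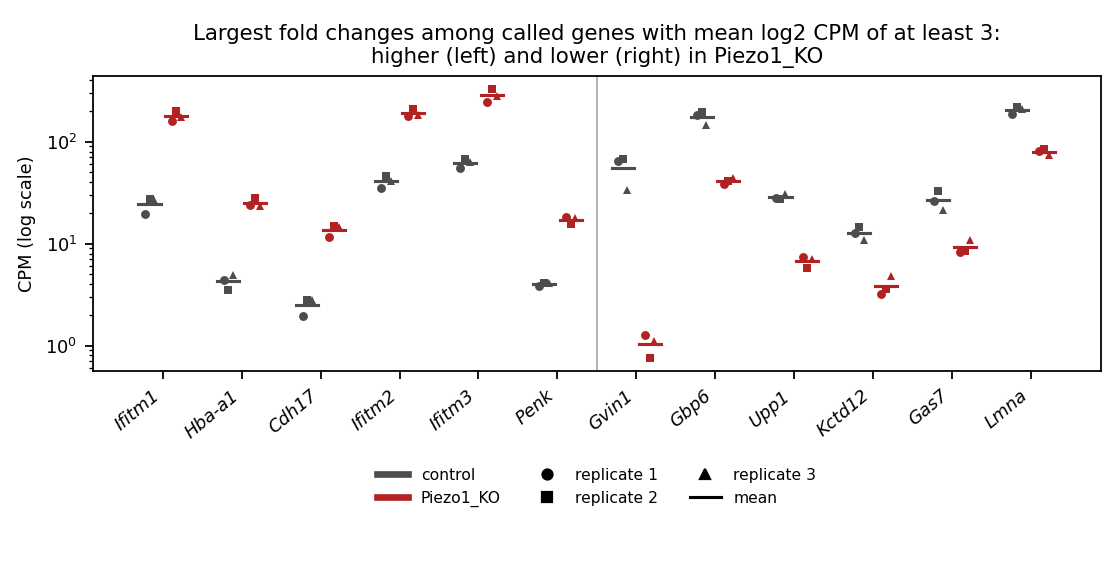
CPM on a log axis in each of the 6 libraries for the 6 genes with the largest rise (left of the grey line) and the 6 with the largest fall (right) in Piezo1_KO among called genes with a mean log2 CPM of at least 3. Symbols mark the replicate, colours the group and bars the group mean. For each gene the 3 libraries of one group lie apart from the 3 of the other, and Gvin1 drops from a mean of 55.4 to 1.05 CPM.

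Secreted effectors and surface receptors were tested through lists fixed before the data were examined. Among 21 tested genes for type 2 and other effector cytokines, 1 rose (Penk), 2 fell and 18 did not pass, or 2 and 3 when adjusted over the list alone. Cxcl3, a neutrophil chemokine, fell from 116 ± 14.9 to 46.1 ± 3.83 CPM, and Csf2, which encodes GM-CSF, from 78.9 ± 16.6 to 36.3 ± 6.50 CPM (SD, n = 3, adjusted p = 0.00242 and 0.0290, edgeR). Of 37 ILC2 identity and receptor genes, 2 rose and 3 fell, or 7 and 6 adjusted over the list alone. Il7r, the IL-7 receptor alpha chain and the locus of the Cre driver, fell from 66.8 ± 8.25 to 32.8 ± 2.03 CPM. Ramp1, part of the CGRP receptor, had a log2 fold change of −1.10 ± 0.14. The genotype labels give Il7r-Cre in both groups, while the titles call the controls WT. The labels do not say whether both groups carry the same number of Il7r-Cre alleles, so the Il7r value is not separable from a difference at that locus. Il17rb, the IL-25 receptor chain, rose by 0.74 ± 0.10 on the log2 scale. Neither list shifted as a whole (camera adjusted p = 0.190 and 0.333).

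Of 28 co-stimulatory and inhibitory receptors, 1 rose and 5 fell, or 8 and 7 adjusted over the list alone. Entpd1, the ectonucleotidase CD39, fell from 11.9 ± 2.14 to 1.70 ± 0.29 CPM (SD, n = 3), and Tnfrsf25 (death receptor 3) and Cd200r1 had log2 fold changes of −0.74 ± 0.12 and −0.53 ± 0.09. Among 22 genes of STAT5 and cytokine feedback, 2 rose and 1 fell, or 4 and 2 adjusted over the list alone, and the rises were in Gzmb (granzyme B) by 1.26 ± 0.15 and Socs3 by 0.91 ± 0.11 on the log2 scale. Of 30 apoptosis and survival genes, 3 rose and 1 fell, or 4 and 1 adjusted over the list alone, and Pim2 and Pmaip1 were among the rises, by 0.81 ± 0.09 and 0.89 ± 0.11. Of 17 glucocorticoid-response genes, Il1r2, the decoy receptor for IL-1, rose 4.08-fold, Mt1 rose by 1.37 ± 0.19 on the log2 scale, and Anxa1 had −1.18 ± 0.12, with the same counts of 2 and 1 adjusted over the list alone. Camera called none of these 4 lists (adjusted p from 0.435 to 0.995).

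Camera called no list tied to mechanical sensing or tissue exit with all 6 libraries, while the mixed form of fry, which tests for change in either direction, passed the channel, YAP/TAZ and KLF2 lists (adjusted p = 0.00326, 0.00357 and 2.26e-05). That form passed 25 of the 28 lists tested, so it does not set these lists apart. Of 34 mechanosensitive and calcium channel genes other than Piezo1, 1 rose (Atp2b4, a plasma membrane calcium pump, by 0.60 ± 0.10), or 4 rose and 1 fell adjusted over the list alone, and 25 had a positive log2 fold change. Of 24 YAP/TAZ and mechanotransduction targets, Wwtr1, which encodes TAZ itself, fell (log2 fold change −1.19 ± 0.20), or 1 rose and 3 fell adjusted over the list alone. Of 27 genes of the KLF2 and tissue egress program, Pecam1 rose by 0.65 ± 0.10 and Foxp1 had −0.63 ± 0.11, or 4 rose and 6 fell adjusted over the list alone. Camera adjusted p was 0.190, 0.786 and 0.846 for these lists, and the channel list passed without control replicate 2 (0.0388). Heat shock and dissociation genes (1 of 19 rose, namely Socs3, or 1 rose and 1 fell adjusted over the list alone) had a camera adjusted p of 0.995.

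Camera called 12 of 28 lists tested, 7 up and 5 down in Piezo1_KO, with a preset inter-gene correlation of 0.01. With the correlation estimated for each list, only the type I interferon response held (adjusted p = 0.0337). That list of 26 genes had a median log2 fold change of −0.43, with 25 of 26 members negative. Of its members 3 fell, or 12 adjusted over the list alone, among them Gbp2 and Zbp1, a sensor of Z-form nucleic acids, at −1.12 ± 0.17 and −0.87 ± 0.14 (adjusted p = 0.0204 and 0.0243, edgeR).

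Among the metabolic lists, glycolysis and cholesterol synthesis were called upward with the preset correlation. Of 28 glycolysis genes, 5 rose and 0 fell, or 13 and 0 adjusted over the list alone, and the median log2 fold change was 0.34. Slc2a3, the glucose transporter GLUT3, rose from 56.3 ± 4.17 to 143 ± 13.6 CPM (SD, n = 3), and Egln3, a prolyl hydroxylase acting on hypoxia-inducible factor, from 20.2 ± 1.39 to 64.3 ± 6.83 CPM. The mitophagy receptor gene Bnip3 rose by 0.84 ± 0.13 on the log2 scale, and Aldoc (aldolase C) and the lactate exporter gene Slc16a3 were the other called members. Of these 5, Slc2a3, Aldoc and Slc16a3 encode transport or enzyme steps of glycolysis. The glycolysis call (camera adjusted p = 9.09e-08) was lost with an estimated correlation (adjusted p = 0.350). It was kept in the other 13 of 14 alternatives, all of which but fry used the preset correlation. Of 25 cholesterol synthesis genes, Cyp51 and Msmo1, both sterol demethylation enzymes, rose by 0.56 ± 0.09 and 0.70 ± 0.12, or 16 rose adjusted over the list alone, with 23 of 25 members positive and a median of 0.42. That call (camera adjusted p = 9.03e-09) was also lost with an estimated correlation (adjusted p = 0.350) and kept in the same other 13 alternatives. Of 31 genes of lipid uptake and fatty acid oxidation, Dgat2 and Acsl3, which act in triglyceride synthesis and fatty acid activation, rose by 0.61 ± 0.10 and 0.53 ± 0.09, or 3 rose and 2 fell adjusted over the list alone, and the list did not shift (camera adjusted p = 0.995). Of 28 TCA cycle genes and 33 mTORC1 and amino acid response genes, 0 passed, or 0 and 0 adjusted over the list alone, and camera called neither (adjusted p = 0.838 and 0.731). The smallest p-values there were those of Me2 and Vldlr, at log2 fold changes of 0.29 ± 0.08 and 0.97 ± 0.23 (adjusted p = 0.145 and 0.109, edgeR).

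**Figure D3:**
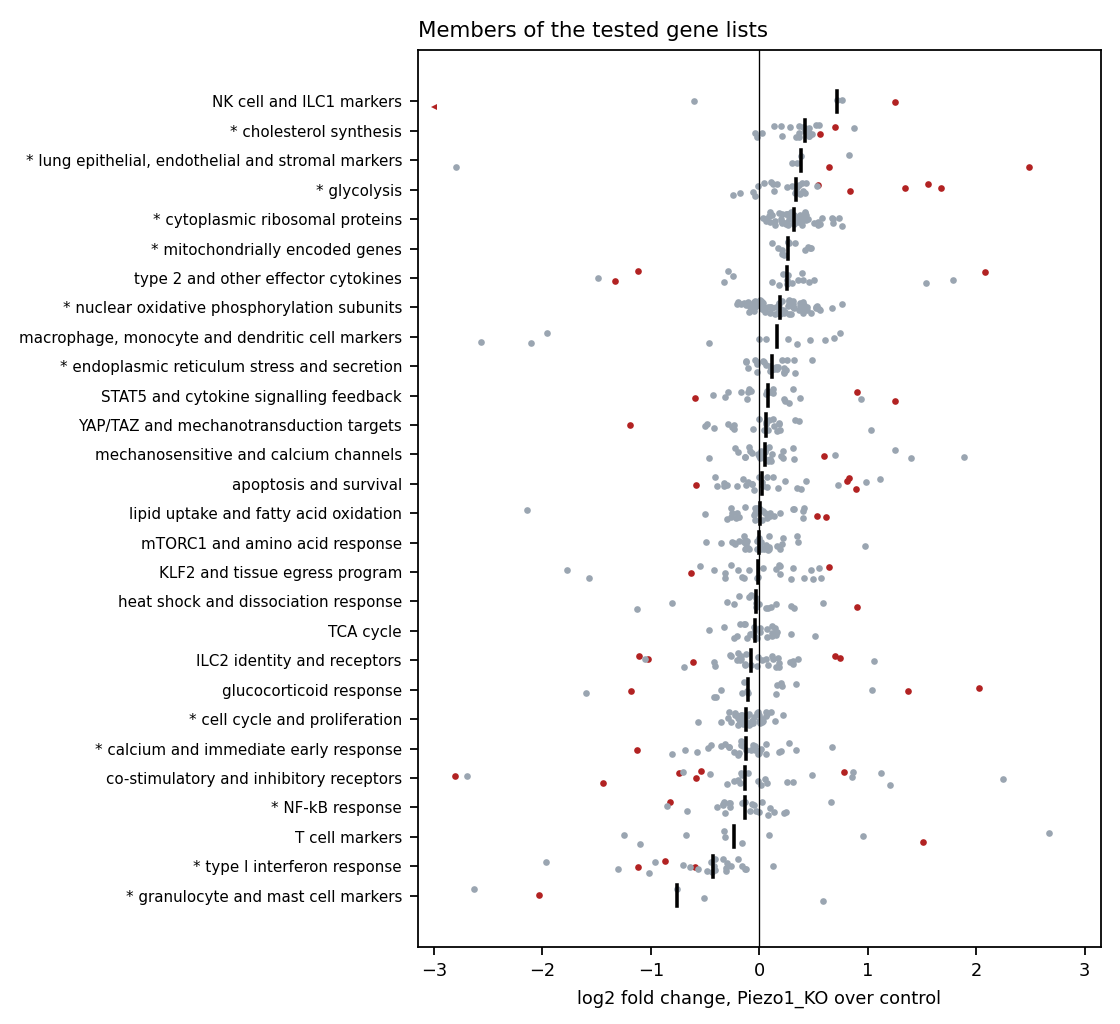
Log2 fold change in Piezo1_KO over control of each tested member of the 28 lists with at least 5 members, sorted by the list median (black bar). Red points passed an adjusted p of 0.05 over all genes, grey points did not, an asterisk marks the 12 lists called by camera with the preset correlation, and a triangle at the edge is Tbx21, which lies beyond the axis. The type I interferon list has a median of −0.43 and the cholesterol synthesis list one of 0.42.

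The remaining lists called upward held no or few genes past the threshold. The 54 cytoplasmic ribosomal protein genes had a median log2 fold change of 0.32 and the 76 nuclear oxidative phosphorylation subunits one of 0.19, with 0 members past the threshold in either, also when adjusted over the list alone. Their members with the smallest p were Rps28 and Ndufa4, at 0.76 ± 0.35 and 0.76 ± 0.20 (adjusted p = 0.405 and 0.139, edgeR). The medians moved with single libraries, to 0.12 and 0.045 without control replicate 2, 0.53 and 0.41 without control replicate 3 and 0.20 and 0.11 without Piezo1_KO replicate 2, and the second to 0.30 without Piezo1_KO replicate 1. Both calls (camera adjusted p = 1.37e-05 and 0.0122) were lost with an estimated correlation (adjusted p = 0.858 and 0.917). They were also lost without control replicate 2 (0.103 and 0.863), in which ribosomal protein genes took 1.33% of the counts against 1.78% to 2.39% in the other 5 libraries, and the second list was also lost without control replicate 1 (0.142) and without Piezo1_KO replicate 2 (0.350). The 13 mitochondrially encoded genes had a median of 0.27 and 0 called members, also over the list alone, with mt-Co3 at 0.42 ± 0.14 (adjusted p = 0.240, edgeR). Their camera call (adjusted p = 0.00197) was lost with an estimated correlation (adjusted p = 0.627). Of 26 endoplasmic reticulum stress and secretion genes 0 passed, or 2 rose adjusted over the list alone, and Ero1l, an oxidase of disulfide bond formation, had a log2 fold change of 0.48 ± 0.10 (adjusted p = 0.0664, edgeR). That call (camera adjusted p = 0.0248) was lost with an estimated correlation (adjusted p = 0.350). It was also lost without control replicate 1 (0.103) or 3 (0.0956), without Piezo1_KO replicate 1 (0.0661) or 2 (0.0563) and with the replicate number as a block (0.0724).

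Lists of proliferation genes and of signalling responses were called downward. Of 44 cell cycle and proliferation genes 0 passed, also over the list alone, 32 were negative and the median was −0.12. The member with the smallest p, E2f1, had −0.56 ± 0.15 (adjusted p = 0.141, edgeR). The call (camera adjusted p = 0.00197) was lost with an estimated correlation (adjusted p = 0.189). The other 13 of 14 alternatives kept it, all but fry with the preset correlation. Of 26 NF-kB response genes, Nfkbiz fell (−0.82 ± 0.13), or 9 fell adjusted over the list alone, and the call (camera adjusted p = 0.00197) had an adjusted p of 0.627 with an estimated correlation and 0.0918 without control replicate 2. Of 33 calcium and immediate early genes, 1 fell, or 2 rose and 3 fell adjusted over the list alone. It was Irf8, a transcription factor of myeloid and lymphoid cells, which fell from 56.1 ± 1.596 to 25.6 ± 1.64 CPM (SD, n = 3, adjusted p = 0.00158, edgeR). Irf8 lies 1.75 Mb from Piezo1 on chromosome 8. This list's call (camera adjusted p = 0.0325) was lost with an estimated correlation (adjusted p = 0.365) and, among 8 of its 14 alternatives in all, without control replicate 2 (0.189) and without Piezo1_KO replicates 2 (0.0562) and 3 (0.101).

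Markers of other cell types did not move in one direction. Of 10 T cell markers, Lck rose from 13.2 ± 1.95 to 37.6 ± 4.34 CPM, or 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.570). Of 5 NK cell and ILC1 markers, Gzmb rose and Tbx21, the transcription factor T-bet, fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.857). Tbx21 was at 1.29 ± 0.22 CPM (SD, n = 3, 20 to 44 counts per library) in control and had 0 counts in all 3 Piezo1_KO libraries, which made it at least 32.7-fold lower against a floor of 3 counts over the group (counting error only). Of 3 B and plasma cell markers, Ighm rose from 18.6 ± 4.40 to 64.9 ± 10.7 CPM, or 2 rose adjusted over the list alone. Of 5 granulocyte and mast cell markers, Cma1 (mast cell chymase) fell from 5.45 ± 1.59 to 1.31 ± 0.42 CPM, or 2 fell adjusted over the list alone, and the list was called down (camera adjusted p = 0.0123, or adjusted p = 0.350 with an estimated correlation). Of 7 lung epithelial, endothelial and stromal markers, Pdgfrb rose from 1.10 ± 0.44 to 6.30 ± 1.44 CPM and Pecam1 also rose, or 2 rose and 1 fell adjusted over the list alone, and the list was called up (camera adjusted p = 0.0281, or adjusted p = 0.350 with an estimated correlation). That call was also lost without control replicate 1 (0.142), without Piezo1_KO replicate 2 (0.0922) and over members of no other list (0.157). Both tested erythroid genes rose, also over the list alone. These were Hba-a1 and Hba-a2. Hba-a2 had 0 counts in the controls against 2.81 ± 0.295 CPM (SD, n = 3), at least 62.4-fold higher against the same floor (counting error only). How reads were divided between these paralogs is uncertain, and the log2 ratio of their sum was 2.73 ± 0.16 (SE). Of 12 macrophage, monocyte and dendritic cell markers (not called by camera), 4 ILC3 markers and 4 sex-linked genes, 0 passed, or 2 of the first rose and 2 of the second fell adjusted over the list alone. H2-Ab1 had the smallest p of the first list and Kdm5d of the last, at log2 fold changes of 0.69 ± 0.18 and −0.13 ± 0.12 (adjusted p = 0.132 and 0.703, edgeR).

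The libraries themselves were not evenly spaced. The first principal component of the 500 most variable genes held 52.8% of their variance. It set control replicate 2 apart from the other 5 libraries. The second held 30.7% and had control replicate 3, the shallowest, at its far end. Along this second component the groups also did not overlap, at 1.43 to 30.9 in control and −13.04 to −11.6 in Piezo1_KO. Pseudogenes took 0.456% of the counts in control replicate 2 against 0.928% to 1.08% elsewhere. Spearman correlations of log2 CPM were 0.992 to 0.994 between Piezo1_KO libraries, 0.969 to 0.987 between control libraries and 0.972 to 0.990 between groups. Control replicate 2 and Piezo1_KO replicate 1 carry the same sample sheet index, 22, so the libraries may come from more than one sequencing run, and which library belongs to which run is not given in the labels. A difference between runs therefore cannot be told apart from the groups.

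**Figure D4:**
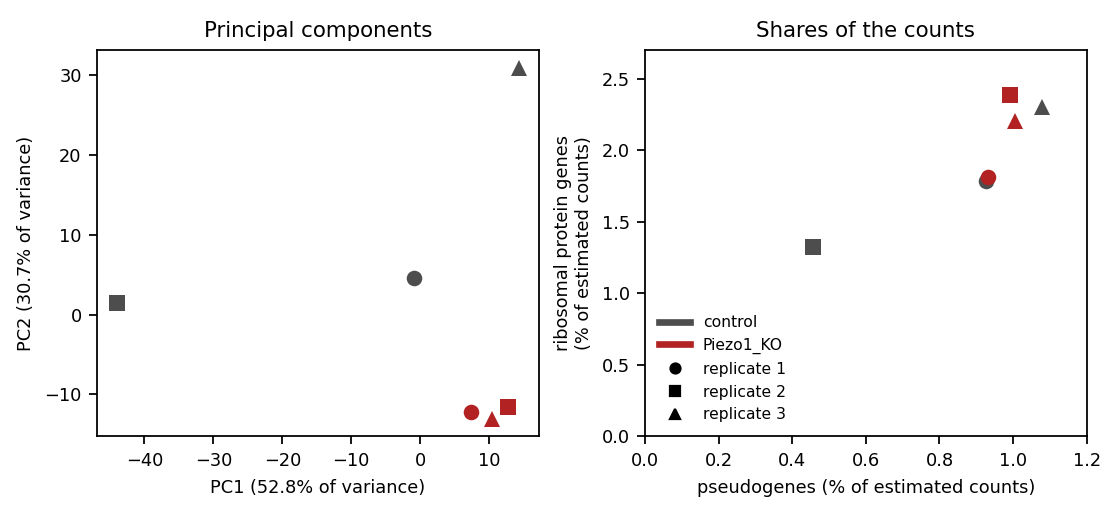
Left, the first and second principal components of log2 CPM for the 500 most variable genes in the 6 libraries. Right, the share of each library's estimated counts taken by pseudogenes and by ribosomal protein genes, in percent. Symbols mark the replicate and colours the group, and control replicate 2 lies apart at 0.456% and 1.33%.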

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

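One alternative, protein-coding genes only, was chosen after the data had been seen. All 214 called genes kept their sign in each of the 14 alternative fits that tested them, and 26 passed in all 14. Since all 214 had no overlap between the groups, a change of sign was hardly possible in refits of these same libraries. The count of 214 genes (142 higher, 72 lower) was 593 (352 and 241) in DESeq2, 439 (267 and 172) in limma-voom with sample quality weights and 392 (256 and 136) with protein-coding genes only, and ranged from 33 to 297 (22 to 209 higher, 10 to 92 lower) without 1 library. It fell without control replicate 1 (34) and without Piezo1_KO replicates 1, 2 and 3 (35, 33 and 53), and not without control replicates 2 (297) and 3 (237). RLE size factors gave 213, no filter 206, the strict filter 247 and robust quasi-likelihood 218, and shared 210, 201, 212 and 211 genes with the 214. A minimum fold of 1.5, which filters the same calls and is not among the 14 fits, left 189 (129 and 60). The log2 fold change of Piezo1 was −0.85 in DESeq2, −0.93 in limma-voom and −0.83 with protein-coding genes only, all past the threshold, and −1.05 to −0.70 without 1 library. The cause was not tested.

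With the replicate number as a replicate block, 52 genes passed (37 higher, 15 lower) and 11 lists. Same-numbered libraries did not deviate together (correlations of −0.023, −0.183 and −0.008), and no library correlated best with its own number. The highest values were those of control replicate 3 with Piezo1_KO replicate 2 (0.209) and control replicate 2 with Piezo1_KO replicate 1 (0.175). Deviations from the mean of 3 libraries depend on each other, so these values do not decide whether any libraries were paired.

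The count of 12 lists fell to 1 with an estimated correlation and was 8 to 15 otherwise. Fry also called the apoptosis list up (adjusted p = 0.0123) and the NK cell and ILC1 list down (0.00766). The median log2 fold change of the NK cell and ILC1 list was 0.72, with 3 of 5 tested members positive, so that call is not a shift of the whole list. Of the lists called by camera, fry did not call those of calcium and immediate early, NF-kB, oxidative phosphorylation, mitochondrially encoded and ribosomal protein genes. Among uncalled lists some medians changed sign, and none passed in a setting where its sign had changed. These were KLF2 and egress (0.044 with the strict filter, 0.014 with protein-coding genes only, −0.074 to 0.072 without 1 library), mTORC1 (0.0028 with no filter, 0.0097 with the strict filter, 0.0097 with the replicate block, 0.018 with protein-coding genes only, −0.066 to 0.020 without 1 library), fatty acid oxidation (−0.0028 over members of no other list, −0.029 to 0.036 without 1 library), heat shock (0.021 over members of no other list, −0.026 to 0.029 without 1 library) and glucocorticoid response (0.033 with the strict filter, −0.155 to 0.0052 without 1 library). Without 1 library, medians ranged from −0.0017 to 0.0659 for channels (past the threshold at the upper end, without control replicate 2), −0.056 to 0.098 for YAP/TAZ, −0.068 to 0.0055 for TCA cycle and −0.050 to 0.0393 for apoptosis. Of the 50 named genes past the threshold, 17 passed in all 14 alternative fits. Depth limits low genes such as Tbx21, which lost its call in 5 of 14.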

Other observations

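The genes of this paragraph were chosen after their values were seen, and no group of them was tested for enrichment. Of 5 genes for fatty acid desaturases and an elongase looked at, 4 passed. Scd1 rose from 5.34 ± 0.62 to 21.3 ± 0.95 CPM (SD, n = 3, adjusted p = 0.000682, edgeR), and Scd2, Fads2 and Elovl6 rose by 1.05 ± 0.14, 1.36 ± 0.16 and 0.71 ± 0.12 on the log2 scale. Fads1, the remaining desaturase, and Fasn, the fatty acid synthase, had log2 fold changes of 0.0017 ± 0.12 and 0.12 ± 0.20 and did not pass (adjusted p = 0.998 and 0.859, edgeR). Epas1, which encodes HIF-2 alpha, rose from 25.1 ± 3.999 to 58.2 ± 0.81 CPM (SD, n = 3). Among other genes linked to hypoxia, Ak4, P4ha1 and Kdm5b rose by 1.23 ± 0.13, 0.57 ± 0.10 and 0.74 ± 0.14 on the log2 scale, while Hif1a, Ldha and Pdk1 had log2 fold changes of −0.18 ± 0.13, 0.26 ± 0.11 and 0.43 ± 0.11 and did not pass (adjusted p = 0.624, 0.379 and 0.141, edgeR). Nqo1 and Gclc, targets of the oxidative stress factor NRF2, fell to 36.1 ± 4.47 and 162 ± 8.14 CPM from 75.0 ± 6.68 and 265 ± 22.4 CPM, and Gclm and Hmox1 had −0.55 ± 0.11 and −0.52 ± 0.11 (adjusted p = 0.0532 and 0.0847, edgeR). The clock genes Nr1d1 and Npas2 fell, at log2 fold changes of −1.28 ± 0.22 and −0.77 ± 0.14, and Nr1d2, the paralog of Nr1d1, had −0.54 ± 0.16 and did not pass (adjusted p = 0.185, edgeR).

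The tests of explanations below were chosen after the results had been seen, except the count of splits. The real grouping gave 214 genes and 12 lists, and the highest among the other splits was 0 genes and 5 lists. In each case 1 of the 10 splits, the real one, gave a result as large, and 10 splits are too few for a share under 0.05.

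Interferon-inducible GTPases, a family chosen after its values were seen, were among the falls. Of 18 tested Gbp, Irg and Gvin family genes, 10 fell, 0 rose and all 18 had a negative log2 fold change, with between 4 and 14 falling under each alternative, while the Ifitm genes Ifitm1, Ifitm2 and Ifitm3, also interferon-inducible, rose under each one. Reads moved between the listed members would leave the family's sum level, and its log2 ratio was −0.84 ± 0.09 (SE). The sum was 1380 CPM in control, of which Gvin1 had 55.4 CPM. It therefore says little about single members such as Gvin1, and nothing about reads shared with genes outside the family list. Variants linked to the Piezo1 allele acting on the members themselves are argued against by their positions, since 0 of the 10 lie within 10 Mb of Piezo1. Interferon gamma in control replicate 2, which holds 24 of the 25 Ifng counts of the controls, is argued against by the 10 of 10 that still passed without that library. Leaving out this library says nothing about interferon gamma signalling shared by all controls, which was not tested. Irf8 was the 1 called gene among 118 tested within 10 Mb of Piezo1, against 211 called among 13797 tested genes placed on a chromosome. An effect through Irf8, a difference in strain background, a difference in Il7r-Cre dosage and an effect of Piezo1 loss were not tested and may each account for the pattern. Strain may also bear on the Ifitm rises and on Nnt, a gene that differs between C57BL/6 substrains. Nnt rose from 28.1 ± 1.77 to 42.6 ± 1.59 CPM (SD, n = 3, adjusted p = 0.0277, edgeR).

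Alpha globin was higher in Piezo1_KO, with Hba-a1 and Hba-a2 together at 27.996 ± 2.84 CPM against 4.26 ± 0.68 CPM in control (SD, n = 3). Red cell RNA would bring beta globin at a similar level, and Hbb-bt had 18 counts in Piezo1_KO, or 0.839% of the 2146 alpha globin counts (0.496% to 1.33%, exact 95% interval, counting error only). Hbb-bs, the other beta globin gene of the erythroid list, was not among the tested genes, being either absent or below the count filter. Its counts were not included, so the value argues against red cell RNA only as far as Hbb-bt stands for beta globin. Reads moved between Hba-a1 and Hba-a2 would leave their sum level, and its log2 ratio was 2.73 ± 0.16 (SE). A hypothesis that remains is transcription of alpha globin in the lymphocytes themselves, which may differ with strain or with Piezo1 and was not tested further.

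Control replicate 2 stood apart by its low share of pseudogene counts, and 41 of the 50 genes at the opposite end of the first principal component were pseudogenes. Its sequencing depth, the greatest of the 6, stays open: thinning it to the total of control replicate 3 left the share at 0.456%, but random thinning keeps a share level whatever its cause and decides nothing, and Piezo1_KO replicate 2, the next in depth, had 0.991%. The ribosomal protein list lost its call without this library (camera adjusted p = 0.103) and kept it without either other control, so that call may rest on control replicate 2. For the oxidative phosphorylation list (adjusted p = 0.863 without it) the contribution of this library cannot be told apart from those of control replicate 1 and Piezo1_KO replicate 2, since the call was also lost without either of them (0.142 and 0.350). A sequencing run or a handling difference stays open, since the labels do not assign libraries to runs.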
